A study of Rattus norvegicus with 12 samples.

How the data were processed

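Bacterial communities were profiled in rat faeces by sequencing part of the 16S rRNA gene, a ribosomal gene whose sequence varies between bacterial taxa. The labels give 4 groups of 3 libraries: Sham (sham-operated), SAH (the subarachnoid haemorrhage model), SAH+Tet (the model with tetrandrine, a plant alkaloid that blocks calcium channels) and SAH+Tet+ABX (the same with ABX, a common short form for antibiotics). Each sample also carries a second treatment label, which names a cell differentiation protocol. It does not match rat faeces, is the same in all groups and was not used. Drugs, doses, times of sampling relative to surgery and housing are not given in the sources used here, and the labels do not say whether each library comes from a separate animal. All p-values therefore measure only the spread between these libraries.

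The deposited values are counts: the authors gave unscaled reads per amplicon sequence variant (ASV), an exact sequence inferred from the reads, each with its lineage. The submitters' processing notes name fastp, which trims and filters reads, and cutadapt, which removes primers. Neither has a version there. The denoiser, chimera filter, primers, 16S region and taxonomy database are not given in the sources used here. Each of these sets how many ASVs are reported and how deep their names go, so richness and the share of unnamed reads hold for this pipeline only. Read shares also depend on the number of 16S gene copies per genome and on DNA extraction, neither of which was corrected. No bacterial load and no blank extraction was available, so every value is relative and a lower share does not by itself mean fewer cells.

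The series table held 7240 ASVs, and its columns were identical to the per-sample tables for all 12 libraries. The 2 ASVs assigned to Eukaryota were left out, which left 7238 ASVs and 384 genus-level features, of which 303 carry a genus name. Reads without a genus name were summed under their deepest named rank and are written here as "unnamed" with that rank. Between 68.5% and 89.2% of the reads of a library carried a genus name. Library totals ranged from 211450 to 531426 reads. They fell into a lower class of 5 libraries (211450 to 248285 reads: SAH 1, SAH+Tet 3 and all 3 of SAH+Tet+ABX) and a higher class of 7 (448795 to 531426 reads), separated at 300000 reads. The labels give 1 date of processing for all libraries and no reason for these depth classes. A count of 0 allows a share of up to 0.0006% to 0.0014% (3 reads of the library). Such limits cover counting error only, because PCR copies are not independent molecules. Replicates differed by far more than counting error: the lowest chi-square per degree of freedom between 2 libraries of 1 group was 69.8.

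Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, TMM scaling, groups as the only term) on genus and on ASV counts. Features needed at least 10 reads in at least 3 libraries of the fit. The comparisons of SAH with Sham and of SAH+Tet with SAH came from 1 fit of the 9 libraries without antibiotics. The comparison of SAH+Tet+ABX with SAH+Tet came from a fit of all 12. Adjusted p-values are Benjamini-Hochberg values over the features tested in each comparison, with a threshold of 0.05. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic of the test. It is not a fitted standard error and gives no interval where a group has few reads. A fold against a group with 0 reads in all its libraries was computed against 3 reads per library and is given as a lower bound. For each comparison, 1 data set with changes and 1 without were simulated from the fitted spread, with 20 genera or 100 ASVs changed at each fold. For SAH against Sham (187 genera), edgeR recovered 55% of genera changed 16-fold and 5% of those changed 4-fold. It recovered 10% and 0% for SAH+Tet against SAH (187 genera), and 25% and 0% for SAH+Tet+ABX against SAH+Tet (195 genera). It recovered 0% of changed ASVs at either fold in each comparison and made 0 calls in unchanged data. With 1 draw of 20 genera per fold, these shares are rough and cannot rank the comparisons by power.

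Fry from limma 3.58.1 was run on 7 sets of genera named before the data were examined: short-chain fatty acid producing Clostridia, lactic acid bacteria and bifidobacteria, Bacteroidales, enterobacteria and other opportunistic Gram-negative genera, opportunistic Gram-positive cocci and clostridia, mucin and sulfate users, and reagent and environmental genera. Of their 142 names, 73 were found. Fry asks whether the members of a list move, on balance, in 1 direction, and its mixed form whether they move in either. Neither compares the list with other genera. Camera, which does, was run with a preset and with an estimated correlation between members.

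Observed ASVs, the Chao1 richness estimate and the Shannon and Simpson diversity indices were means of 100 random draws of 211450 reads per library. Community distances were Bray-Curtis distances of ASV shares. Groups were compared by exact permutation: PERMANOVA for distances and the one-way F statistic for single measures, over all 15400 arrangements of 12 libraries into 4 groups, 280 arrangements of 9 into 3 groups, or 10 of 6 into 2 groups. All are 2-sided. The smallest p these allow is 6.49e-05, 0.00357 and 0.1, so no comparison of 3 libraries with 3 could reach 0.05. Phyla and families with a mean share of at least 0.1% were tested on log10 shares with 0.0001 added. In 1000 simulated data sets without an effect, 6.6% of the PERMANOVA p-values and 4.9% of those of the F statistic were under 0.05. The number of data sets was raised to 1000 after a first, smaller run had given a higher share for PERMANOVA. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

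Named taxa were chosen by a rule fixed before the data were examined: the 10 genera with the highest mean share, up to 12 that rose and 12 that fell per comparison by mean share, the 6 with the smallest p where fewer than 6 passed, up to 4 members per list, the 2 ASVs with the smallest p in each direction, the 6 most abundant phyla and the 10 most abundant families. Alternatives fixed at the same time were library-size and TMMwsp scaling, DESeq2 1.42.0 with poscounts size factors, limma on centred log-ratio values with 0.5 reads added, no filter on low counts, a minimum of 50 reads, other sets of groups in the fit, rarefied counts, the replicate number as a block, other distances and each library left out. Keeping the 2 ASVs assigned to Eukaryota and leaving out reads without a genus name were also among them. Depth class as a block, tests within 1 depth class and removal of 8 aerobic Gram-positive families were added after the data had been seen. So were rarefied distances and leaving out libraries for lists, phyla and families.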

Results

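Faecal samples of rats were sequenced to learn whether the composition of the gut microbiota differed among sham-operated animals, animals with experimental subarachnoid haemorrhage, and animals with haemorrhage given tetrandrine alone or with antibiotics. The data were read counts of 16S rRNA gene variants in 12 libraries, 3 for each of the groups Sham, SAH, SAH+Tet and SAH+Tet+ABX. The Sham libraries held 495890, 498430 and 519889 reads, and the SAH libraries 248285, 531426 and 448795. The SAH+Tet libraries held 458015, 516810 and 227301 reads, and the SAH+Tet+ABX libraries 211450, 234185 and 244856. SAH 1, SAH+Tet 3 and all 3 SAH+Tet+ABX libraries thus formed a lower depth class, and values within a depth class, or of single libraries of each class, are given for richness, Shannon diversity, the counts of genera and ASVs called and the genera that open each comparison. Phyla, families and lists were tested over both classes together. A count of 0 allows a share of up to 0.0006% to 0.0014%, depending on the library.

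Firmicutes and Bacteroidota, the phyla that make up most of the rat gut community, were the most abundant in every group. Firmicutes took 74.7% ± 5.77 of reads in Sham (mean ± SD, n = 3 throughout), 66.5% ± 12.2 in SAH, 69.0% ± 2.86 in SAH+Tet and 66.4% ± 18.3 in SAH+Tet+ABX. Bacteroidota took 17.9% ± 3.66, 22.8% ± 5.11, 20.95% ± 2.52 and 29.9% ± 16.7. The ratio of Firmicutes to Bacteroidota was 4.33 ± 1.12, 3.14 ± 1.41, 3.31 ± 0.250 and 3.67 ± 3.91, and its logarithm did not differ among the groups (exact permutation p = 0.728, but 0.0218 without SAH+Tet+ABX 1). Muribaculaceae (15.3% of reads on average), Lactobacillus (14.6%) and unnamed Lachnospiraceae (13.3%) were the most abundant genus-level features. Romboutsia (5.19%), the Lachnospiraceae NK4A136 group (3.58%), Ruminococcus (3.17%), Corynebacterium (3.11%), unnamed Oscillospiraceae (2.18%), Alloprevotella (1.98%) and unnamed Bacilli (1.85%) followed.

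Of the phyla and families tested, 4 phyla and 17 families differed among the groups after adjustment (exact permutation of the F statistic). Verrucomicrobiota, whose main gut genus Akkermansia degrades mucin, held 2.86% ± 2.45 of reads in Sham, 0.106% ± 0.0972 in SAH, 0.0333% ± 0.0371 in SAH+Tet and 1.18% ± 0.829 in SAH+Tet+ABX (adjusted permutation p = 0.0205, but 0.0508 with a smaller added constant and 0.0799 without a logarithm). Desulfobacterota, which include sulfate reducers, held 0.532% ± 0.0556, 0.442% ± 0.140, 0.640% ± 0.188 and 0.000272% ± 0.000472 (adjusted permutation p = 0.0205). Campilobacterota, here almost all Helicobacter, held 0.331% ± 0.186, 0.348% ± 0.168 and 0.627% ± 0.200 in the groups without antibiotics and had 0 reads in SAH+Tet+ABX (adjusted permutation p = 0.0205). Patescibacteria, very small bacteria that live on other bacteria, held 0.320% ± 0.109, 0.182% ± 0.125, 0.103% ± 0.0583 and 0.00178% ± 0.000915 (adjusted permutation p = 0.0205). Depth class was not a term in these tests. SAH 1 and SAH+Tet 3, of the lower class, held 0.0379% and 0.0400% of Patescibacteria. The other libraries of these groups held 0.113% to 0.255%. For Verrucomicrobiota the shares were 0.00161% and 0.00176%, against 0.0240% to 0.194%. Desulfobacterota and Campilobacterota did not split by depth class within SAH and SAH+Tet. Among the families, Sutterellaceae held 0.102% ± 0.0504 in Sham, 0.446% ± 0.155 in SAH, 0.0898% ± 0.0402 in SAH+Tet and 0.602% ± 0.497 in SAH+Tet+ABX (adjusted permutation p = 0.0424, but 0.0557 with a larger added constant and 0.125 without a logarithm). Erysipelatoclostridiaceae were also higher in SAH and SAH+Tet+ABX than in the other groups, with 0.0306% ± 0.0187, 0.402% ± 0.137, 0.0331% ± 0.0157 and 0.452% ± 0.227 (adjusted permutation p = 0.0226, but 0.0769 without a logarithm). Oscillospiraceae held 7.37% ± 1.06, 4.63% ± 0.962, 7.77% ± 1.60 and 2.41% ± 0.828 (adjusted permutation p = 0.0121), and Ruminococcaceae 5.91% ± 2.06, 5.15% ± 0.613, 6.90% ± 1.18 and 2.09% ± 1.16 (adjusted permutation p = 0.0227). Lachnospiraceae (24.1% of reads on average), Muribaculaceae, Lactobacillaceae (14.6%), Prevotellaceae (5.56%), Peptostreptococcaceae (5.20%), Corynebacteriaceae (3.11%) and Erysipelotrichaceae (2.39%) did not pass. Actinobacteriota and Proteobacteria, with 3.95% and 1.37% of reads, did not pass either. On shares without a logarithm, 13 phyla and families passed in place of 21.

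ASV richness was lowest in SAH+Tet+ABX. At 211450 reads per library, 2271 ± 61.8 ASVs were observed in Sham, 1756 ± 522 in SAH, 2066 ± 642 in SAH+Tet and 573 ± 117 in SAH+Tet+ABX (exact permutation p = 0.0112 over the 4 groups). Chao1 was 2334 ± 63.9, 1805 ± 559, 2121 ± 685 and 577 ± 119 (exact permutation p = 0.0124). The Shannon index was 5.57 ± 0.169, 5.32 ± 0.490, 5.54 ± 0.349 and 4.43 ± 0.470 (exact permutation p = 0.0339). That call was lost when any of 7 libraries was left out: Sham 1 (0.0537), Sham 2 (0.0502), Sham 3 (0.0561), SAH+Tet 1 (0.0504), SAH+Tet 2 (0.0552), SAH+Tet+ABX 1 (0.0982) or SAH+Tet+ABX 2 (0.0562), all exact permutation p-values. The Simpson index was 0.984 ± 0.00426, 0.973 ± 0.0185, 0.985 ± 0.00318 and 0.968 ± 0.0192 and did not pass (exact permutation p = 0.303).

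Between SAH and Sham the mean number of observed ASVs differed by -514.8, and between SAH+Tet+ABX and SAH+Tet by -1493, with no overlap of the groups (exact permutation p = 0.1 each, the smallest possible). SAH+Tet exceeded SAH by 310.2 ASVs, with overlapping groups (exact permutation p = 0.5). That difference was 15.1 without SAH 1, 510.3 without SAH 2, 101.8 without SAH+Tet 1, 148.7 without SAH+Tet 2 and 680.0 without SAH+Tet 3, and the one between SAH and Sham was -219.7 without SAH 1. Richness went with depth class even at 1 common depth: SAH 1 had 1166 ASVs, against 2156 and 1946 in the other SAH libraries, and SAH+Tet 3 had 1327, against 2483 and 2389. Within a depth class the differences were -219.7 (2 SAH against 3 Sham libraries), 384.9 (2 SAH+Tet against 2 SAH) and -753.1 (3 SAH+Tet+ABX against SAH+Tet 3). The Shannon index differed by -0.248 between SAH and Sham (exact permutation p = 0.6), and by 0.0276 within the higher depth class. SAH+Tet exceeded SAH by 0.222 (exact permutation p = 0.6), and by 0.124 within the higher class. SAH+Tet+ABX differed from SAH+Tet by -1.12 (exact permutation p = 0.1), and by -0.760 within the lower class.

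**Figure D1:**
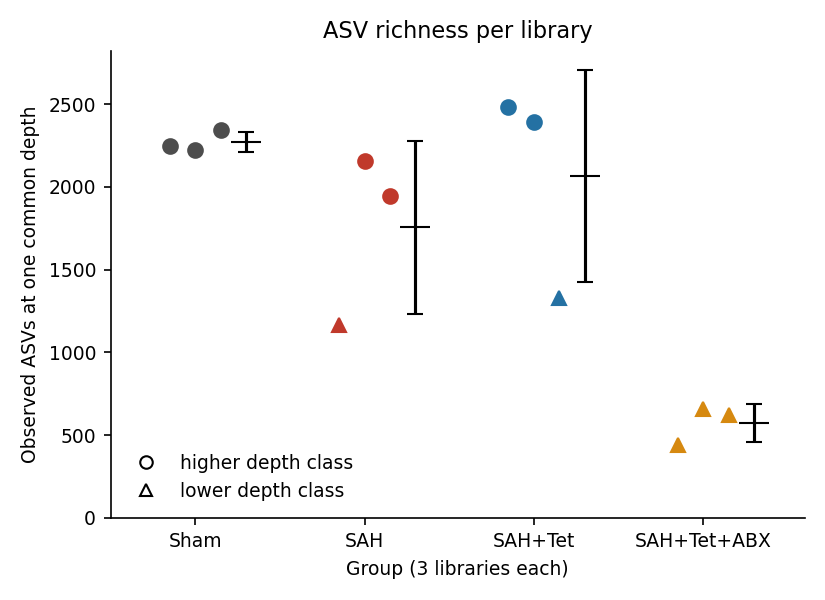
Observed ASVs per library at 211450 reads, by group, with circles for the higher and triangles for the lower depth class; bars give the mean and SD of 3 libraries. The 3 SAH+Tet+ABX libraries lie between 440.0 and 659.5, below every other library.

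Community composition separated the 4 groups. The groups accounted for 52.9% of the variation in Bray-Curtis distances of ASV shares (exact permutation p = 6.49e-05, the smallest the 15400 arrangements allow). Without SAH+Tet+ABX they accounted for 48.1% (exact p = 0.00357, again the smallest possible, and 0.0278 with the replicate number as a block). With depth class as a block the 4-group test gave p = 0.000476 (exact) and 42.2%, and with replicate number as a block p = 0.00174 (exact). In pairs, the groups accounted for 47.2% of the variation for SAH and Sham, 37.8% for SAH+Tet and SAH and 42.8% for SAH+Tet+ABX and SAH+Tet, each with an exact p of 0.1, the smallest possible. At genus level the exact p for SAH+Tet and SAH was 0.3. Mean distances within a group were 0.451 ± 0.129 in Sham, 0.484 ± 0.155 in SAH, 0.553 ± 0.124 in SAH+Tet and 0.629 ± 0.186 in SAH+Tet+ABX, and 0.781 ± 0.0319 between SAH+Tet+ABX and SAH+Tet. The mean distance to the Sham libraries was 0.655 ± 0.0240 for SAH and 0.626 ± 0.0269 for SAH+Tet. This difference of -0.0295 did not pass (exact permutation p = 0.3). It was -0.0579 without Sham 1, -0.0138 without Sham 2, -0.0169 without Sham 3, -0.0169 without SAH 1 and -0.0450 without SAH+Tet 3, and -0.0699 at genus level (exact permutation p between 0.2 and 0.5).

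**Figure D2:**
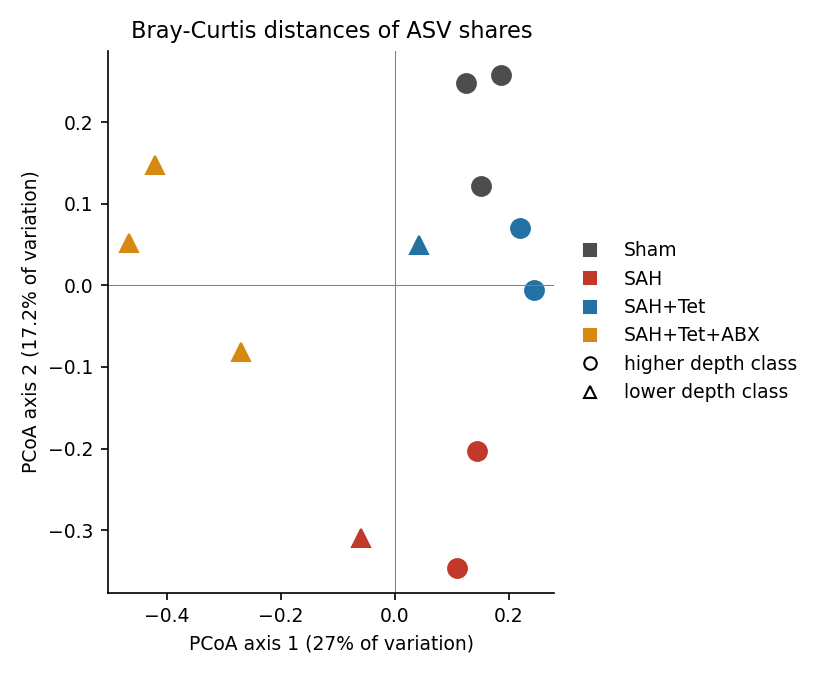
Principal coordinates of the Bray-Curtis distances between the 12 libraries, coloured by group, with circles for the higher and triangles for the lower depth class. Axis 1 holds 27.0% of the variation and sets the SAH+Tet+ABX libraries apart, and axis 2 holds 17.2% and sets the SAH libraries apart from Sham.

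SAH was compared with Sham for the effect of the haemorrhage model. Escherichia-Shigella, facultative anaerobes that include gut pathogens, held 0.145% ± 0.117 of reads in SAH and 0.00333% ± 0.00155 in Sham (log2 fold change 5.51 ± 1.13 SE), and every SAH library lay above every Sham library. Corynebacterium, aerobic Gram-positive rods, held 6.56% ± 5.66 in SAH and 0.00785% ± 0.00351 in Sham (9.82 ± 2.71). Its share was 10.2% and 9.40% in SAH 2 and SAH 3 but 0.0451% in SAH 1. The mean share of Candidatus Arthromitus, the segmented filamentous bacteria, was 0.0313% ± 0.0160 and 0.00309% ± 0.00122 (3.52 ± 0.74). Candidatus Stoquefichus held 0.137% ± 0.0354 and 0.0218% ± 0.0155 (2.89 ± 0.70), and the [Bacteroides] pectinophilus group 0.220% ± 0.169 and 0.0110% ± 0.0131 (4.58 ± 1.13). Collinsella had 0 reads in Sham and 0.0107% ± 0.000221 in SAH, at least 17.98-fold higher. Escherichia-Shigella held 0.183% and 0.238% in SAH 2 and SAH 3 but 0.0129% in SAH 1. Within the higher depth class the log2 fold changes were 6.27 for Escherichia-Shigella, 10.67 for Corynebacterium, 3.51 for Candidatus Arthromitus, 2.79 for Candidatus Stoquefichus and 4.03 for the [Bacteroides] pectinophilus group, and Collinsella was not tested there.

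In edgeR, 0 of 187 genera passed for SAH against Sham, and the lowest adjusted p was 0.0927. At an unadjusted p below 0.05 there were 55. DESeq2 called 50 (30 higher, 20 lower) and limma on centred log-ratio values 9 (4 higher, 5 lower). With depth class as a block, an alternative added after the data had been seen, 26 passed (22 rose, 4 fell), and within the higher depth class also 26. Those 22 included Corynebacterium (adjusted p = 0.000585), Escherichia-Shigella (0.00479), Candidatus Arthromitus (0.0176), Collinsella (0.0262) and Candidatus Stoquefichus (0.0429), and the 4 included Akkermansia (0.0425) and Turicibacter (0.0425), all from edgeR. Of the 26, 9 belonged to the aerobic Gram-positive families described at the end. Some outside these families also had nearly all their SAH reads in SAH 2 and SAH 3. Enterococcus held 0.00201%, 0.141% and 0.158% in SAH 1, 2 and 3, and Weissella, Pediococcus, Proteus and Psychrobacter had 0 reads in SAH 1. Candidatus Arthromitus (0.0338%, 0.0141% and 0.0459%) and Collinsella (0.0105%, 0.0109% and 0.0107%) were not limited to them. SAH 1 is the only library of SAH and Sham in the lower depth class. In the fit of 9 libraries, only SAH 1 and SAH+Tet 3 are in that class. The depth term therefore takes up how these libraries differ from the others of their groups. Without SAH 1, Escherichia-Shigella passed (edgeR adjusted p = 0.0325), and without SAH 3 ASF356 of the Lachnospiraceae did (0.0475), a genus named after its value was seen. In 66 genera (35.3%) the groups did not overlap, where 10% is the share expected by chance. Genera that vary together within libraries can also separate together. The share was not counted for other splits, so its excess over 10% was not tested.

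The enterobacteria and other opportunistic Gram-negative genera moved up as a list (fry adjusted p = 0.0161), with all 5 tested members above 0 in log2 fold change. Camera, which sets the list against the other genera, gave an adjusted p of 0.380 with an estimated correlation. Of these members, 0 passed over all genera and 2 rose adjusted over the list alone. Parasutterella held 0.446% ± 0.155 in SAH and 0.102% ± 0.0504 in Sham, Helicobacter 0.347% ± 0.168 and 0.330% ± 0.187, and Rodentibacter 0.00735% ± 0.00311 and 0.00699% ± 0.00393. The list's adjusted p was 0.0610 without Sham 2, 0.0652 without Sham 3 and 0.0986 with the replicate number as a block. The lactic acid bacteria and bifidobacteria also moved up (fry adjusted p = 0.0292; 0 of 6 passed, and 0 adjusted over the list alone). The fry adjusted p of that list was 0.0622 with library-size scaling, and between 0.0540 and 0.151 without any 1 of the libraries other than SAH 3. Camera with an estimated correlation gave an adjusted p of 0.380. Lactobacillus, which ferments sugars to lactate, held 17.4% ± 8.38 in SAH and 11.4% ± 4.37 in Sham, and Weissella 0.329% ± 0.286 and 0.000321% ± 0.000555. Weissella had 0 reads in SAH 1 and held 0.522% and 0.465% in SAH 2 and SAH 3, and Pediococcus likewise had 0 reads in SAH 1 and held 0.0913% and 0.0971%. Lactobacillus (26.5%) and Streptococcus (0.381%) were highest in SAH 1 among the SAH libraries.

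The opportunistic Gram-positive cocci and clostridia moved in both directions (fry adjusted p = 0.133 for 1 direction and 0.00122 for either). Of 9 members, 0 passed over all genera, and 5 rose and 1 fell adjusted over the list alone. Their summed share was 5.77% ± 2.75 in SAH and 10.1% ± 2.74 in Sham, opposite in sign to the list's median log2 fold change of 2.88. Turicibacter held 0.368% ± 0.289 and 2.10% ± 0.0925. The cocci were high in SAH 2 and SAH 3 only: in SAH 1, 2 and 3 Aerococcus held 0.00201%, 0.528% and 0.477%. Jeotgalicoccus held 0.00322%, 0.538% and 0.496%, Enterococcus 0.00201%, 0.141% and 0.158%, and Staphylococcus 0.0109%, 0.0802% and 0.0758%. Candidatus Arthromitus (0.0338%, 0.0141% and 0.0459%) and Erysipelatoclostridium (0.0306%, 0.0164% and 0.0196%) did not show this split. The mucin and sulfate users gave a fry adjusted p of 0.110 (0.0462 without SAH 3), with 0 of 4 past either adjustment, and Akkermansia held 0.0259% ± 0.0231 in SAH and 2.77% ± 2.33 in Sham. The short-chain fatty acid producing Clostridia (fry adjusted p = 0.690 for 1 direction and 0.0168 for either) had 0 of 21 past either adjustment. The Lachnospiraceae NK4A136 group held 1.90% ± 0.506 and 4.73% ± 0.562, Roseburia 3.29% ± 1.86 and 2.44% ± 0.684, and Blautia 3.00% ± 2.65 and 0.176% ± 0.210. The Bacteroidales (0.897, with 0 of 15 past either adjustment) had a median log2 fold change of 0.25 and a summed share of 21.3% ± 4.24 against 16.7% ± 2.99, although fry's direction was down. The reagent and environmental genera (0.133) had 0 of 5 past the threshold over all genera and 1 that rose adjusted over the list alone.

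At ASV level, 0 of 2283 passed in edgeR, with 552 at an unadjusted p below 0.05. With depth class as a block 0 passed, and within the higher depth class also 0. DESeq2 called 404, limma on centred log-ratio values 270, and edgeR on the 6 libraries alone 304. A Ruminococcus ASV and a Muribaculaceae ASV had 0 reads in Sham and 0.226% ± 0.0664 and 0.227% ± 0.0467 of reads in SAH, at least 379-fold and 382-fold higher. An Oscillospiraceae ASV and a Lachnospiraceae ASV, neither with a genus name, held 0.0209% ± 0.0101 and 0.0166% ± 0.00527 in Sham and had 0 reads in SAH, at least 25.6-fold and 20.4-fold lower. All 4 had an edgeR adjusted p of 0.110.

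SAH+Tet was compared with SAH for the effect of tetrandrine in animals with haemorrhage. The Lachnospiraceae NK4A136 group, which includes butyrate producers, held 5.62% ± 1.53 of reads in SAH+Tet and 1.90% ± 0.506 in SAH (log2 fold change 1.49 ± 0.33 SE). Blautia held 0.0907% ± 0.0436 and 3.00% ± 2.65 (-5.19 ± 1.29), and Candidatus Stoquefichus 0.0159% ± 0.00543 and 0.137% ± 0.0354 (-3.18 ± 0.71). Unnamed Coriobacteriales held 0.00524% ± 0.00173 and 0.0292% ± 0.00930 (-2.52 ± 0.46). Fusicatenibacter and Collinsella had 0 reads in SAH+Tet and 1.01% ± 1.06 and 0.0107% ± 0.000221 in SAH, at least 1187-fold and 12.6-fold lower. Fusicatenibacter held 2.12% in SAH 1, of the lower depth class, 0.900% in SAH 2 and 0.00936% in SAH 3, and without SAH 1 the bound was 534-fold. In each of these 6 genera the SAH+Tet libraries did not overlap the SAH libraries, as in 44 of all 187 (23.5%). The share expected by chance is 10%, but an excess over it was not tested, as for SAH against Sham. Within the higher depth class the log2 fold changes were 1.47 for the Lachnospiraceae NK4A136 group, -4.44 for Blautia, -3.11 for Candidatus Stoquefichus and -2.73 for unnamed Coriobacteriales, and Collinsella was not tested there.

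In edgeR, 0 of 187 genera passed for SAH+Tet against SAH, with 33 at an unadjusted p below 0.05 and a lowest adjusted p of 0.0969. DESeq2 called 32 (9 higher, 23 lower) and limma on centred log-ratio values 1, Collinsella. With depth class as a block, edgeR called 1, unnamed Coriobacteriales (adjusted p = 0.0257). Within the higher depth class it called Staphylococcus (0.0137), and without SAH 3 it called ASF356 of the Lachnospiraceae (0.0177). At ASV level 0 of 2283 passed in edgeR, with 474 at an unadjusted p below 0.05, and DESeq2 called 301 and limma on centred log-ratio values 112. With depth class as a block edgeR called 0 ASVs, and within the higher depth class also 0. A Lachnospiraceae NK4A136 group ASV and a Monoglobus ASV had 0 reads in SAH and 0.729% ± 0.951 and 0.124% ± 0.140 in SAH+Tet, at least 896-fold and 152-fold higher (221-fold without SAH+Tet 2, and 54.1-fold without SAH+Tet 3). A Clostridia UCG-014 ASV and a Ruminococcus ASV held 0.0399% ± 0.00285 and 0.251% ± 0.120 in SAH and had 0 reads in SAH+Tet, at least 46.8-fold and 294-fold lower. All 4 had an edgeR adjusted p of 0.179.

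The lactic acid bacteria and bifidobacteria moved down as a list in SAH+Tet (fry adjusted p = 0.0283), with 0 of 6 members past either over all genera or adjusted over the list alone. Camera, which sets the list against the other genera, gave an adjusted p of 0.442 with an estimated correlation. The fry adjusted p was above 0.05 with library-size scaling (0.0557) and with the replicate number as a block (0.293). It was also above 0.05 without SAH 2 (0.0983), SAH 3 (0.0901), SAH+Tet 2 (0.191) or SAH+Tet 3 (0.0713). Lactobacillus held 10.7% ± 4.25 in SAH+Tet, against 17.4% ± 8.38 in SAH, Bifidobacterium 0.0610% ± 0.0606 against 0.674% ± 0.504, Streptococcus 0.109% ± 0.0405 against 0.246% ± 0.118, and Weissella 0.00723% ± 0.00736 against 0.329% ± 0.286. The other lists did not pass in 1 direction, with fry adjusted p-values of 0.861 (short-chain fatty acid producing Clostridia), 0.861 (Bacteroidales), 0.232 (enterobacteria; 0.0187 without SAH 1), 0.771 (Gram-positive cocci and clostridia), 0.365 (mucin and sulfate users) and 0.365 (reagent genera). In either direction, the Clostridia (0.00333), the Gram-positive cocci and clostridia (0.00825) and the enterobacteria (0.0386) passed. Adjusted over the list alone, 1 of the Clostridia rose and 2 fell, 2 of the Gram-positive genera fell and 2 of the enterobacteria fell, with 0 in the other lists. The list of Gram-positive genera had a median of 0.07 and a summed share of 9.87% ± 5.90 against 5.77% ± 2.75, although fry's direction was down. In SAH+Tet 1, 2 and 3, its members Staphylococcus and Jeotgalicoccus held 2.36%, 3.92% and 0.00704%, and 1.38%, 2.09% and 0.00264%. The high shares of both thus lay in SAH+Tet 1 and SAH+Tet 2. Summed shares were also opposite in sign to fry's direction for the Clostridia (14.8% ± 3.74 against 16.4% ± 5.74), the Bacteroidales (20.02% ± 2.94 against 21.3% ± 4.24) and the reagent genera (6.81% ± 5.33 against 7.33% ± 5.73).

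Across the 187 genera, the log2 fold changes of SAH against Sham and of SAH+Tet against SAH correlated at -0.422. Because both share the SAH libraries with opposite sign, 100 simulations without group differences gave -0.508 ± 0.101 (SD), ranging from -0.708 to -0.247, so the observed correlation lay within that range. Genera are not independent replicates. Signs were opposite in 71.1% of the genera, against 66.3% in the simulations. The covariance was -4.69, against -1.34 ± 0.416. Over 2283 ASVs the correlation was -0.592, below the range of 50 simulations, -0.567 to -0.471. All these simulations drew each genus or ASV independently. Taxa that vary together within libraries would widen the simulated ranges, so the simulations cannot show a reversal beyond the shared SAH libraries. In SAH+Tet and Sham, Blautia held 0.0907% ± 0.0436 and 0.176% ± 0.210, Candidatus Stoquefichus 0.0159% ± 0.00543 and 0.0218% ± 0.0155, and Parasutterella 0.0898% ± 0.0402 and 0.102% ± 0.0504. Akkermansia held 0.0176% ± 0.0263 in SAH+Tet and 2.77% ± 2.33 in Sham.

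SAH+Tet+ABX was compared with SAH+Tet for the effect of adding antibiotics, and 74 of 195 genera passed in edgeR (18 rose, 56 fell). Helicobacter, Gram-negative bacteria of the gut mucus, fell from 0.627% ± 0.200 of reads to 0 reads in all 3 SAH+Tet+ABX libraries, at least 480-fold lower (adjusted p = 0.000745). Prevotella, which ferments plant polysaccharides, fell from 1.23% ± 1.06 to 0.000712% ± 0.00123 (log2 fold change -10.50 ± 2.32 SE, adjusted p = 0.00874). Roseburia, a butyrate producer, fell from 0.925% ± 0.519 to 0.00399% ± 0.00690 (-7.68 ± 1.86, adjusted p = 0.0131). Akkermansia rose from 0.0176% ± 0.0263 to 1.18% ± 0.829 (6.33 ± 2.23, adjusted p = 0.0465), and Blautia rose from 0.0907% ± 0.0436 to 2.21% ± 2.35 (4.78 ± 1.32, adjusted p = 0.0189). In each of these 5 genera the libraries of the groups did not overlap. In SAH+Tet 3, the SAH+Tet library of the lower depth class, Helicobacter held 0.855%, Prevotella 0.0462%, Roseburia 0.365% and Blautia 0.0832%, and Akkermansia had 0 reads.

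Among the other genera that rose, unnamed Peptococcaceae went from 0.114% ± 0.0568 to 0.640% ± 0.276, Parasutterella from 0.0898% ± 0.0402 to 0.602% ± 0.497 and GCA-900066575 of the Lachnospiraceae from 0.103% ± 0.0120 to 0.436% ± 0.163. The [Ruminococcus] gnavus group (0.833% ± 1.07), Fusicatenibacter (0.736% ± 1.26), Frisingicoccus (0.361% ± 0.131) and Flavonifractor (0.241% ± 0.178) had 0 reads in SAH+Tet and were at least 978-, 864-, 424- and 283-fold higher. Without SAH+Tet+ABX 3 the bounds were 256-fold for the [Ruminococcus] gnavus group, 12.3-fold for Fusicatenibacter and 174-fold for Flavonifractor, and Fusicatenibacter had 0 reads in SAH+Tet+ABX 1 as well. The [Clostridium] innocuum group (0.229% ± 0.211 from 2 reads), Lachnospiraceae UCG-010 (0.183% ± 0.139 from 0.00768% ± 0.00286) and Candidatus Stoquefichus (0.135% ± 0.0578 from 0.0159% ± 0.00543) also rose.

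Among those that fell, Clostridia UCG-014 went from 2.44% ± 1.31 to 0.00284% ± 0.00491 and UCG-005 of the Oscillospiraceae from 2.75% ± 1.15 to 0.0419% ± 0.0472. The NK4A214 group of the Oscillospiraceae went from 0.742% ± 0.192 to 0.0996% ± 0.0719, and unnamed Ruminococcaceae from 1.66% ± 0.311 to 0.382% ± 0.189. Unnamed Prevotellaceae (0.730% ± 0.448), Prevotellaceae UCG-003 (0.665% ± 0.586) and Facklamia (1.38% ± 1.30) fell to 0 reads, at least 558-, 508- and 1051-fold lower (372-fold for unnamed Prevotellaceae without SAH+Tet 1, and 586-fold for Facklamia without SAH+Tet 2). Corynebacterium went from 5.85% ± 5.29 to 0.00666% ± 0.00611, Staphylococcus from 2.09% ± 1.97 to 0.0166% ± 0.0107 and Jeotgalicoccus from 1.16% ± 1.06 to 2 reads. In SAH+Tet 3 alone, these held 0.0106%, 0.00704% and 0.00264%, Facklamia held 0.000880% and Prevotellaceae UCG-003 had 0 reads, so that the means of these 5 genera rest on SAH+Tet 1 and SAH+Tet 2. Against the SAH+Tet+ABX libraries, SAH+Tet 3 alone gave a log2 fold change of 1.14 for Staphylococcus.

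Of the 74 genera, 41 had 0 reads in all SAH+Tet+ABX libraries and 8 had 0 reads in all SAH+Tet libraries. Among all 195 tested, these counts were 68 and 12. In 60 of the 74 the groups did not overlap, and over all 195 genera they did not overlap in 82 (42.1%). The share expected by chance is 10%, but the excess over it was not tested here either. The balance of directions moved on centred log-ratio values, where 42 genera rose and 33 fell, 50 of them among the 74. Genus by genus, the log2 fold changes there were higher than with TMM by a median of 2.25. Library-size scaling in edgeR moved them by a median of -0.08 (17 genera rose, 57 fell), and with TMMwsp 18 rose and 55 fell. Centred log-ratio values also differ from TMM in the reads added to counts, so scaling was not shown to be the cause. DESeq2 called 105 (38 rose, 67 fell). On centred log-ratio values unnamed Ruminococcaceae turned to 0.11. With depth class as a block 45 passed (8 rose, 37 fell), 43 of them among the 74, and with the replicate number as a block 45, all among the 74. Within the lower depth class only SAH+Tet 3 stands against the 3 SAH+Tet+ABX libraries, and a genus with 0 reads in SAH+Tet+ABX cannot meet the filter there. The 0 of 104 genera that passed in edgeR (9 at an unadjusted p below 0.05) therefore do not show whether the calls depend on depth class. The number of genera called was 49 without SAH+Tet 1, 45 without SAH+Tet+ABX 2 and 49 without SAH+Tet+ABX 3. Of the 74, 37 passed whichever library of both groups was left out, and 34 of these also passed with each block. By direction, 34 of the 56 that fell and 3 of the 18 that rose passed in every leave-out, and 32 and 2 of them also with each block. Some of those that rose had too few libraries with reads to be tested once a SAH+Tet+ABX library was left out. These were the [Ruminococcus] gnavus group, Flavonifractor, the [Clostridium] innocuum group, Faecalitalea, Holdemania and Eisenbergiella. All but Eisenbergiella passed in each of the 3 leave-outs in which they were tested. The genera that passed in every leave-out and with each block include Helicobacter, Prevotella, Roseburia, Clostridia UCG-014, unnamed Prevotellaceae and Frisingicoccus. Of the 24 genera named by abundance, 6 passed in every leave-out and 8 with depth class as a block. The number of the 24 that passed was 14, 15 and 20 without SAH+Tet 1, 2 and 3, and 17, 10 and 11 without SAH+Tet+ABX 1, 2 and 3. Blautia was not past the threshold without SAH+Tet 1, SAH+Tet 2 or SAH+Tet+ABX 3 (highest edgeR adjusted p = 0.0717), nor Akkermansia without SAH+Tet 2, SAH+Tet 3, SAH+Tet+ABX 2 or SAH+Tet+ABX 3 (0.128).

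**Figure D3:**
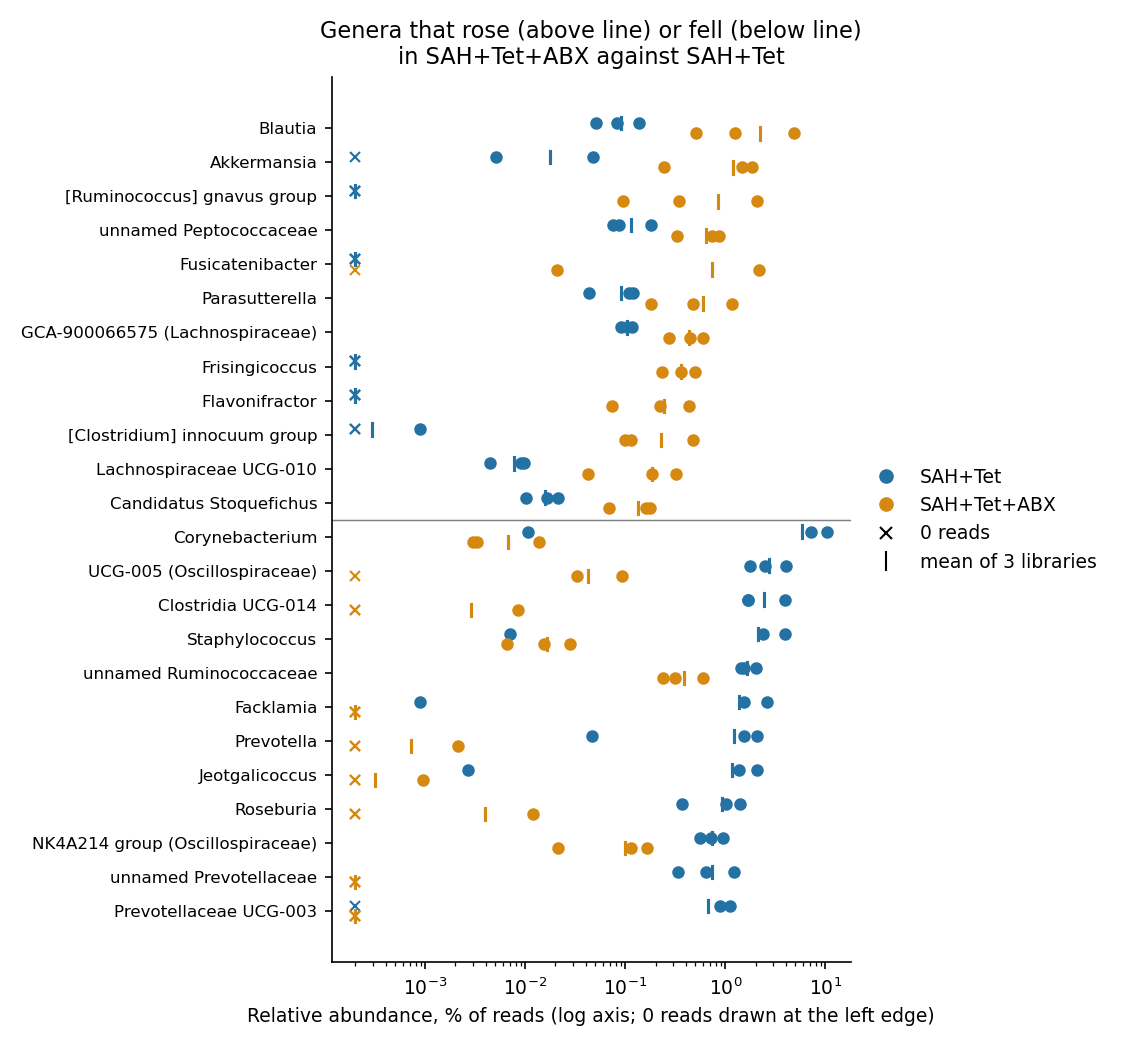
Relative abundance per library, in percent of reads on a log axis, of the 12 most abundant genera that rose (above the line) and the 12 that fell (below it) in SAH+Tet+ABX against SAH+Tet; bars are means of 3 libraries and crosses at the left edge are libraries with 0 reads. Corynebacterium, Staphylococcus, Facklamia and Jeotgalicoccus were at or below 0.0106% in SAH+Tet 3 as well, and Prevotellaceae UCG-003 had 0 reads there.

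Fry was again run by list, and camera, which sets each list against the other genera, beside it. The short-chain fatty acid producing Clostridia moved down (fry adjusted p = 0.00487, camera 0.929 with an estimated correlation). Of 21 members, 6 fell and 2 rose. Roseburia, Acetatifactor and 4 Eubacterium groups fell, while Blautia and Fusicatenibacter rose. The Bacteroidales moved down (fry adjusted p = 0.00965, camera 0.929 with an estimated correlation), with 7 of 15 lower. Those lower included Prevotella, Parabacteroides, which fell from 0.0671% ± 0.0265 to 2 reads, and Barnesiella, which fell from 0.0112% ± 0.00404 to 0 reads. The most abundant member of the list, Muribaculaceae, held 25.1% ± 13.3 against 12.5% ± 4.34. It did not pass in edgeR (adjusted p = 0.104, but 0.0121 in limma on centred log-ratio values). The summed share of the list was 29.7% ± 16.6 against 20.02% ± 2.94. The mucin and sulfate users moved down (fry adjusted p = 0.0146, but 0.0622 without SAH+Tet+ABX 1, and camera 0.929 with an estimated correlation). Desulfovibrio, Bilophila and Mucispirillum fell to 0 reads from 0.0655% ± 0.0443, 0.0290% ± 0.0116 and 0.0291% ± 0.0368, and Akkermansia rose, so that the summed share was 1.18% ± 0.829 against 0.141% ± 0.103. The enterobacteria and other opportunistic Gram-negative genera moved down (fry adjusted p = 0.0371, camera 0.929 with an estimated correlation). Helicobacter was lower and Parasutterella higher among 5, with a median log2 fold change of 0.60. The fry call was lost with the replicate number as a block (0.0688) and without SAH+Tet 1 (0.0764), SAH+Tet 2 (0.0501), SAH+Tet+ABX 1 (0.105) or SAH+Tet+ABX 2 (0.277).

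The opportunistic Gram-positive cocci and clostridia did not move in 1 direction (fry adjusted p = 0.904; 6.71e-06 for either direction). Erysipelatoclostridium rose from 0.00469% ± 0.00331 to 0.111% ± 0.0216. Clostridioides, the genus of C. difficile, rose from 0 reads to 0.00510% ± 0.000592, at least 5.98-fold, but passed with only 1 of the 6 libraries left out. Staphylococcus, Jeotgalicoccus and Aerococcus fell, of 10 members. Of the 6 leave-outs, Staphylococcus passed in 4, Jeotgalicoccus in 3 and Aerococcus, with 0 reads in SAH+Tet 3, in only 1. The summed share of the list was 8.17% ± 4.96 against 9.87% ± 5.90, although fry's direction was up. Romboutsia held 7.01% ± 4.31 against 4.33% ± 1.85 and did not pass. The lactic acid bacteria (0.186, and 0.0460 without SAH+Tet 3) had 1 of 6 lower, Lactococcus, and a summed share of 20.1% ± 13.4 against 10.9% ± 4.27. The reagent and environmental genera (0.0571, and 0.00942 without SAH+Tet 3) had 2 of 5 lower, Corynebacterium and Psychrobacter. In these 7 lists, the counts adjusted over the list alone were equal to those over all genera.

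At ASV level, 247 of 2394 passed in edgeR (14 rose, 233 fell), 231 of them with 0 reads in all SAH+Tet+ABX libraries. Of all 2394 ASVs tested, 1863 had 0 reads in these libraries. A Muribaculaceae ASV rose from 0.00286% ± 0.00370 to 3.47% ± 1.501 (log2 fold change 9.77 ± 2.04 SE, adjusted p = 0.0179), and a Frisingicoccus ASV rose from 0 reads to 0.361% ± 0.131. An ASV of the Lachnospiraceae NK4A136 group (1.34% ± 1.15) and one of unnamed Desulfovibrionaceae (0.382% ± 0.197) fell to 0 reads (adjusted p = 0.0170 each), at least 1026-fold (634-fold without SAH+Tet 2) and 292-fold lower. The count moved with single libraries: it was 0 without SAH+Tet+ABX 3, 69 without SAH+Tet+ABX 1, 78 without SAH+Tet+ABX 2, 144 without SAH+Tet 1, 146 without SAH+Tet 2 and 493 without SAH+Tet 3. DESeq2 called 886, and limma on centred log-ratio values 234 (115 rose, 119 fell). There the log2 fold changes were higher than with TMM by a median of 5.41. With depth class as a block 145 passed, and within the lower depth class, under the same limits as for genera, 0 of 329, with 33 at an unadjusted p below 0.05.

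A set of 8 families of aerobic or facultative Gram-positive bacteria, among them Corynebacteriaceae, Staphylococcaceae and Aerococcaceae, took a large share in part of the libraries; the set was chosen after the shares had been seen. Their summed share was 0.0278%, 0.0560% and 0.0285% in the Sham libraries. In SAH it was 13.5% and 12.4% in SAH 2 and SAH 3, of the higher depth class, and 0.0991% in SAH 1, of the lower. In SAH+Tet it was 13.6% and 20.7% in SAH+Tet 1 and SAH+Tet 2, of the higher class, and 0.0431% in SAH+Tet 3. In SAH+Tet+ABX it was 0.143%, 0.0303% and 0.0596%. Corynebacterium had the highest share among their genera in SAH (6.56% ± 5.66) and SAH+Tet (5.85% ± 5.29), and Staphylococcus held 0.0556% ± 0.0388 in SAH and 2.09% ± 1.97 in SAH+Tet. Without these families, edgeR called 0, 0 and 68 genera in the 3 comparisons, and the 4 groups accounted for 53.1% of the variation in distances (exact permutation p = 6.49e-05).

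**Figure D4:**
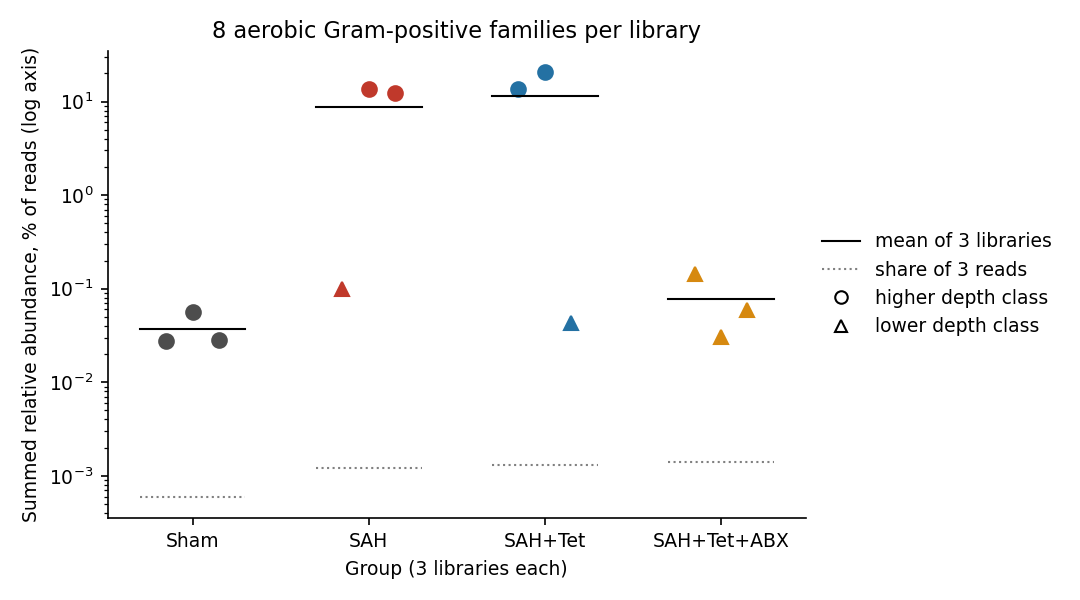
Summed relative abundance of the 8 aerobic Gram-positive families per library, in percent of reads on a log axis, by group, with circles for the higher and triangles for the lower depth class; solid lines are means of 3 libraries and dotted lines the share of 3 reads in the library of fewest reads. SAH 2, SAH 3, SAH+Tet 1 and SAH+Tet 2 lie between 12.4% and 20.7%, and the other 8 libraries at or below 0.143%.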

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

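The count over other splits of the libraries and the richness test without the most abundant genus were set before their results were seen, and the other tests of richness and of the aerobic families were chosen after. Reads assigned to Eukaryota, which the comparisons leave out, were looked at because such reads lay above the Sham libraries in 1 library. SAH+Tet 1 held 5 of them, 0.00109% of its reads, against 0.00101% (5 reads) in Sham 1, the highest Sham library. SAH+Tet 3 held 2 (0.000880%) and the other 9 libraries 0. The read counts of SAH+Tet 1 and Sham 1 were equal, and their shares differ only through the library totals.

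The aerobic Gram-positive families, led by Corynebacterium, took 12.4% to 20.7% of reads in SAH 2, SAH 3, SAH+Tet 1 and SAH+Tet 2, and little elsewhere. Too few reads in SAH 1 and SAH+Tet 3 were argued against, since the lowest of the 4 libraries held 124.9 times the higher of these 2, whose shares lay above that of 3 reads. So were a background common to the higher-depth libraries (221.1 times the highest Sham library) and the haemorrhage in every animal, since the lowest SAH or SAH+Tet library held 0.770 times the highest Sham library. A candidate explanation is 1 outside source mixed into both libraries of a group: the SD of the log2 ratio between SAH 2 and SAH 3 was 0.275 over 32 ASVs of these families and 1.28 over 921 others, and between SAH+Tet 1 and SAH+Tet 2 it was 0.392 over 39 and 1.40 over 977 (ratio of SDs at most 0.280). The families were chosen after their high shares in these 4 libraries had been seen. That choice favours a small spread, so the ratio of SDs does not decide for this source. No blank or housing record is given, so a bloom shared by animals kept together also stays open.

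ASV richness was lowest in SAH+Tet+ABX, where Helicobacter, unnamed Prevotellaceae and most of the ASVs that fell had 0 reads. Fewer reads were argued against as the whole cause: at 1 common depth, the lower of SAH 1 and SAH+Tet 3 had 1.77 times the ASVs of the highest SAH+Tet+ABX library. So was a dominant taxon taking the reads: without the most abundant genus of each library, which in SAH+Tet+ABX was Lactobacillus or Muribaculaceae, the lowest SAH+Tet library had 1.99 times the ASVs of the highest SAH+Tet+ABX library. The loss of taxa under antibiotics, which the design names, may account for the pattern and stays a hypothesis. A part that goes with the depth class stays open, because SAH 1 and SAH+Tet 3 were also poorer in ASVs than the other libraries of their groups at that depth.

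Splits of 3 against 3 libraries number 10, too few for a share under 0.05. For SAH+Tet+ABX against SAH+Tet, the real split gave 74 genera and 247 ASVs, and the highest other split 0 in both (1 of the 10 splits gave as many). For SAH against Sham and for SAH+Tet against SAH, the real split gave 0 genera and 0 ASVs in edgeR and the highest other split 0 (10 of the 10 gave as many). At an unadjusted p below 0.05, those comparisons had 55 genera and 552 ASVs, and 33 genera and 474 ASVs. DESeq2 called 50 genera and 404 ASVs, and 32 genera and 301 ASVs, and limma on centred log-ratio values called 9 and 270, and 1 and 112.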

How the results depend on the processing

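The settings with depth class as a block or within 1 depth class, those without the aerobic families, rarefied distances, and leaving out libraries for lists, phyla and families were chosen after the data had been seen. Of 1614 values over 106 results, 1290 counted as unchanged. Fold changes and lists had to keep direction and side of the threshold, p-values over several groups their side, and differences only their sign. Counts had to stay within a fixed ratio, and the correlation of fold changes within the simulated SD. Pairwise PERMANOVA counted as unchanged in every setting, so this part of the 1290 was fixed beforehand. Keeping the 2 Eukaryota ASVs put back 12 reads and gave the same counts of genera and ASVs called as the main setting. That setting could hardly move any value. A named taxon not tested in a setting was left out of the values and not counted as changed. For the values below that changed, the cause was not tested. For SAH against Sham, where edgeR called 0 genera and 0 ASVs (55 and 552 at an unadjusted p below 0.05), DESeq2 called 50 genera and 404 ASVs, limma on centred log-ratio values 9 and 270, and edgeR 26 genera with depth class as a block and 26 within the higher class. Without a filter it called 160 ASVs, and 304 with the 2 groups alone. For SAH+Tet against SAH (0 and 0; 33 and 474 unadjusted), DESeq2 called 32 genera and 301 ASVs, limma 1 and 112, and edgeR without a filter 90 ASVs. A minimum of 50 reads, rarefied counts, the depth block and the higher depth class gave 1 genus each. For SAH+Tet+ABX against SAH+Tet, the 74 genera became 43 with the 2 groups alone, 45 with the replicate block and 45 with the depth block. The 247 ASVs became 155 with library-size scaling, 135 with TMMwsp, 886 with DESeq2, 523 at 50 reads, 422 with the 2 groups alone, 849 with rarefied counts, 99 with the replicate block and 145 with the depth block. Within the lower class edgeR called 0 of 104 genera (9 unadjusted) and 0 of 329 ASVs (33 unadjusted), but that test sets 1 library, assumed to vary like the others, against 3 and cannot include taxa with 0 reads in SAH+Tet+ABX, so it says nothing on whether the calls hold. Library-size scaling moved log2 fold changes by a median of -0.13 (genera) and -0.11 (ASVs) for SAH against Sham. The median shift was 0.13 (ASVs) for SAH+Tet against SAH and 0.18 (ASVs) for SAH+Tet+ABX against SAH+Tet. With centred log-ratios it was -0.73 and 0.77 in the first comparison and 0.15 and -0.32 in the second.

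Of the 7 lists, 2, 1 and 4 passed fry in the 3 comparisons. Library-size scaling left 1 and 0 in the first and second, the replicate block 0 and 0, and camera 0 in each, with the preset and with the estimated correlation. Some lists that did not pass turned direction: the Clostridia for SAH+Tet against SAH with the replicate block (0.293), and the Gram-positive cocci and clostridia for SAH+Tet+ABX against SAH+Tet with library-size scaling (1.000) and the replicate block (0.880). Camera gave upward directions in the antibiotic comparison for the enterobacteria (0.929 estimated, 0.919 preset), lactic acid bacteria (0.929, 0.723) and reagent genera (0.929, 0.919), all adjusted p-values. The Shannon difference between SAH and Sham turned to 0.0276 within the higher class, 13 phyla and families passed on shares without a logarithm, and the correlation of fold changes was -0.59 over ASVs. Within the lower depth class Staphylococcus had a log2 fold change of 1.14, and unnamed Ruminococcaceae one of 0.11 on centred log-ratios.

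With each library left out in turn, genus counts ranged over 0–1, 0–1 and 45–80 in the 3 comparisons, ASV counts over 0–0, 0–0 and 0–493, and lists past the threshold over 0–3, 0–2 and 2–6. The exact permutation p over the 4 groups spanned 0.0267–0.0982 for Shannon, 0.000779–0.0464 for observed ASVs and 0.0218–0.893 for the log ratio of Firmicutes to Bacteroidota. That log2 ratio ranged from -0.0385 to 0.51 for SAH+Tet against SAH and from -1.23 to 0.0868 for SAH+Tet+ABX against SAH+Tet, and the Shannon difference from -0.440 to 0.0276 for SAH against Sham and from -0.0541 to 0.413 for SAH+Tet against SAH. Adjusted fry p-values of Bacteroidales ranged over 0.573–0.866 and 0.760–0.955 in the first and second comparison, of Gram-positive cocci and clostridia over 0.284–0.852 in the second and 0.227–0.966 in the antibiotic comparison, and of the Clostridia over 0.434–0.990 in the second. Between 14 and 26 phyla and families passed. Replicate numbers were not taken as pairs in the main fits. Fold changes of libraries with the same number correlated at 0.07 to 0.10, -0.59 to 0.50 and -0.01 to 0.14, against -0.12 to 0.05, -0.63 to 0.72 and -0.18 to 0.12 for other numbers. For SAH against Sham, all 3 libraries correlated best with their own number, and 1 did in each of the other comparisons. The correlations are low, but pairing by number stays open for SAH against Sham. Depth sets the floor of 3 reads, so genera under 0.0014% cannot be told from absent ones in the smallest library.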

Other observations

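The families and the genus described here were chosen after their values were seen, and so were both tests of Pseudomonas, the first of which was reworded, and its outcome read differently, after its value was known. Selenomonadaceae, anaerobes that form propionate, held 1.14% ± 0.578 of reads in Sham, 0.312% ± 0.180 in SAH, 0.479% ± 0.245 in SAH+Tet and 0.000699% ± 0.000649 in SAH+Tet+ABX (mean ± SD, n = 3; adjusted permutation p = 0.0154 over the 4 groups). Monoglobaceae, which ferment pectin, held 1.32% ± 0.123, 0.846% ± 0.102, 1.15% ± 0.191 and 0.144% ± 0.202 (adjusted permutation p = 0.0121). The Clostridia vadinBB60 group held 0.306% ± 0.0263, 0.145% ± 0.0347, 0.160% ± 0.0481 and 0.0142% ± 0.0148 (adjusted permutation p = 0.0121). Butyricicoccaceae, which include butyrate producers, held 0.286% ± 0.0494, 0.285% ± 0.144, 0.396% ± 0.0362 and 0.923% ± 0.559 (adjusted permutation p = 0.0227). Peptococcaceae held 0.151% ± 0.0611, 0.170% ± 0.0350, 0.165% ± 0.0672 and 0.661% ± 0.291 (adjusted permutation p = 0.0403, but 0.0547 without a logarithm).

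The p-2534-18B5 gut group, a family of Bacteroidales, held 1.25% and 0.967% of reads in SAH 2 and SAH 3, 0.00121% in SAH 1 and at most 0.00155% in any other library, and did not pass (adjusted permutation p = 0.0782). Spirochaetaceae held 0.764% ± 0.554 in Sham, 0.0430% ± 0.0423 in SAH and 0.363% ± 0.336 in SAH+Tet and had 0 reads in SAH+Tet+ABX (adjusted permutation p = 0.0802, but 0.0478 with a smaller added constant). Acidaminococcaceae held 0.912% and 0.430% in SAH 1 and SAH 2 and had 0 reads in SAH 3, and held 0.00109%, 0.171% and 0.264% in SAH+Tet 1, 2 and 3 (adjusted permutation p = 0.142).

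Pseudomonas, water and soil bacteria that also occur in reagents, held 0.855% of reads on average, with a coefficient of variation of 16.3% over the 12 libraries, the lowest of 154 genera. Rhodococcus (21.1%), the Rhizobium group (21.6%), the [Eubacterium] coprostanoligenes group (24.6%) and unnamed Rhizobiaceae (26.9%) followed. Its share was 0.815% ± 0.162 in SAH+Tet+ABX and 0.868% ± 0.139 in the other 9 libraries, a ratio of 0.939, which argues against a fixed background at DNA extraction together with over 1.5 times less bacterial DNA after antibiotics. An unchanged bacterial load or a background from PCR reagents stays open. That 1 source carries Pseudomonas and the other reagent genera without Corynebacterium may hold or not: Spearman's rho over 12 libraries was 0.399 (permutation p = 0.201) and Pearson's r -0.0271 (permutation p = 0.915), and without the 2 farthest libraries they were 0.406 and -0.0133 (n = 10).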
